A study of Mus musculus with 9 samples.

How the data were processed

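Chromatin was precipitated from fixed mouse spermatocytes with a rabbit antibody against HSF1 or a goat antibody against HSF2, and normal goat serum served as the mock, per the labels' protocols. From 30 µg of chromatin sheared to 100 to 500 bp, 3 µg of the HSF1 or 5 µg of the HSF2 antibody was used, and 80 nucleotides were sequenced from each fragment. Heat shock was started by adding medium warmed to 53 °C or 60 °C, which brought the cells to 38 °C or 43 °C, and cells heated for 5, 10 and 20 min were combined. The series' design text states 2 ChIP replicates per sample, and how they were combined is not given in the sources used here. The mock serum is from the species of the HSF2 antibody and not of the HSF1 antibody, so the background of a rabbit antibody was not measured. Of the 9 samples, the 6 with an HSF1 or HSF2 antibody have peak lists, and the 3 mock libraries enter only as the authors' controls. The read files of all 9 were not used here.

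Reads were processed with Bowtie2, SAMtools and HOMER on build mm10, per the submitters' processing notes. Peaks were called with MACS, per the file headers, each list against the mock library of its own temperature, per the library numbers in the names of the deposited files. The version and thresholds of the peak caller are not given in the sources used here. The authors deposited for each list the peak positions with a score, and a table of the annotation of each peak. The score is the peak caller's value per peak, as deposited by the authors. The deposited files do not name its scale, and its lowest value was 50.0 to 50.15 in the 6 lists. The distance of each peak to the nearest TSS in bp, negative upstream, the annotation class and the nearest gene were deposited by the authors as well, per the file headers. The positions and scores of the 6086 peaks were compared between both kinds of file, and 0 differed. No reads or depths were used, so the precision of a single peak is unknown, and the length of a list depends on read depth and on the mock.

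From these files the number, width and covered length of peaks, the share of peaks per annotation class, and the overlap of lists were computed. Shares have Wilson 95% intervals, and for a share of 0 the limit is 3 counts of the total. Lists of a pair shared a peak where they overlapped by at least 1 bp, counted in peaks of the shorter list. Chance overlap came from 1000 random placements of the longer list within its chromosomes, with a fixed seed, on the assembled nuclear chromosomes. Chromosome lengths were taken as the last base seen in a gene or a peak. A gene had a peak if the authors' annotation gave it as the nearest promoter of a peak within 5 kb of its TSS. The overlap of independent gene lists was n1 × n2 / N, where N is 26220 genes with a curated RefSeq transcript in the GRCm38.p6 gene table, the same build as mm10. Of 6078 peaks with a gene ID, 6053 matched the table. Ranks run from the highest score, and tied scores were ordered by chromosome and position.

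The groups, the comparisons, the 15 gene lists and the rule for named genes were fixed before the data were examined. So were the alternatives listed below, while 3 more alternatives, and all but 1 of the tests of explanations, were chosen after. Of 520 symbols in the gene lists 517 matched the gene table. For each list, the number of members with a peak was set against 10000 random gene lists of the same size, as a description of these libraries, with the mean for such lists calculated from the numbers of genes. The rule named up to 30 heat shock genes, those in most lists first, then by best rank. It also named per list the 5 highest scoring peaks within 5 kb of a TSS and the 3 highest anywhere, up to 10 genes per change with heat by rank, and up to 5 members of each other list. A few genes that the rule names are not described here, and they stay in all counts of lists. The overlap count, the placements and the random gene lists were first tested on simulated data. Of 50 overlaps planted between the HSF1 peaks at 38 °C, 419 in number, and a random list of the widths of the HSF1 peaks at 43 °C, 50 were recovered. The mean of 200 placements was 0.095 where 0.104 was calculated. A gene list with 12 planted members, drawn from 26220 genes, was reached by 0% of random lists, and a list without planted members by 76.45%.

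Alternatives were the upper part of each list by score, equal list lengths, lists without peaks on chromosome Y, on unplaced sequence or in simple, low complexity, satellite or ribosomal RNA repeats (interspersed and 7SL RNA repeats were kept), lists without peaks found everywhere, other overlap rules, other distances to the TSS, and placements that keep the share of peaks near a TSS. The gene table gives no strand, so these placements took an end of each gene at random as its TSS. Counts of heat shock elements in peaks were planned and not run, since no genome sequence was used here. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.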

Results

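Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the heat shock factors HSF1 and HSF2 lay on the genome of mouse spermatocytes, the germ cells in meiosis. HSF1 is the main transcription factor of the heat shock response, and HSF2 is a related factor that is abundant in the testis. The cells came from adult FVB/N males, with 20 mice in an isolation, and held up to 80% spermatocytes. They were either left at 32 °C, the physiological temperature of the testis, or heated to 38 °C or 43 °C for 5, 10 and 20 min, with the 3 times pooled. Each antibody therefore gave 3 peak lists, 6 in all, and 3 mock precipitations with normal goat serum, one temperature each, served as the authors' controls. Each group had 1 list, so no difference between lists has a replicate check, no p-value is given, and every interval covers counting error only. The read depth of the libraries is unknown here. The score of each peak is the authors' own and is used only to rank peaks inside a list.

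The first question was how the number of peaks differed between temperatures for each factor. For HSF1 the lists held 1568 peaks in untreated cells, 419 at 38 °C and 1646 at 43 °C, so the untreated list was 3.74 times as long as the 38 °C list and about as long as the 43 °C list. For HSF2 the numbers were 1284 in untreated cells, 762 at 38 °C and 407 at 43 °C, and the untreated list was 3.15 times as long as that at 43 °C. Peaks were narrower at 43 °C for both factors. The median width for HSF1 was 269 bp in untreated cells, 199 bp at 38 °C and 127 bp at 43 °C, and for HSF2 it was 235, 246 and 126 bp in the same order. The peaks covered 425 kb, 97.4 kb and 271 kb for HSF1 and 294 kb, 193 kb and 67.2 kb for HSF2. Many peaks of the 43 °C lists carried the same score: the 2 commonest scores belonged to 46.8% of the HSF1 peaks and 61.4% of the HSF2 peaks at 43 °C, against 11.6% to 23.9% in the other 4 lists.

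Heat shock genes were the clearest group of genes near the peaks, and they were most numerous in the HSF1 list at 43 °C. Of 158 genes in the 6 heat shock lists, which cover the HSP70, HSP90, DNAJ and small heat shock protein families with their partners, other heat shock targets and the heat shock factors themselves, 25 had an HSF1 peak within 5 kb of the transcription start site (TSS) at 43 °C. There were 12 in the untreated HSF1 list and 12 at 38 °C, but the untreated list is the longer. With 407 top peaks per list, cut by position where scores tied, the counts were 7, 12 and 19 in untreated cells, at 38 °C and at 43 °C. For HSF2 there were 9 in untreated cells, 7 at 38 °C and 0 of 158 at 43 °C, and a count of 0 among 407 peaks allows a share of up to 0.737% of peaks. Random gene lists of the same size would hold on average 1.51 such genes for HSF1 in untreated cells, 0.591 at 38 °C and 1.67 at 43 °C, and 0.964, 0.506 and 0.235 for HSF2. None of 10000 random lists had more than 8 such genes for any list of peaks. In all, 35 of the 158 genes had a peak in at least 1 list, 13 had peaks in 2 or more, 10 had peaks for both antibodies, and 14 were in the HSF1 list at 43 °C alone.

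**Figure D1:**
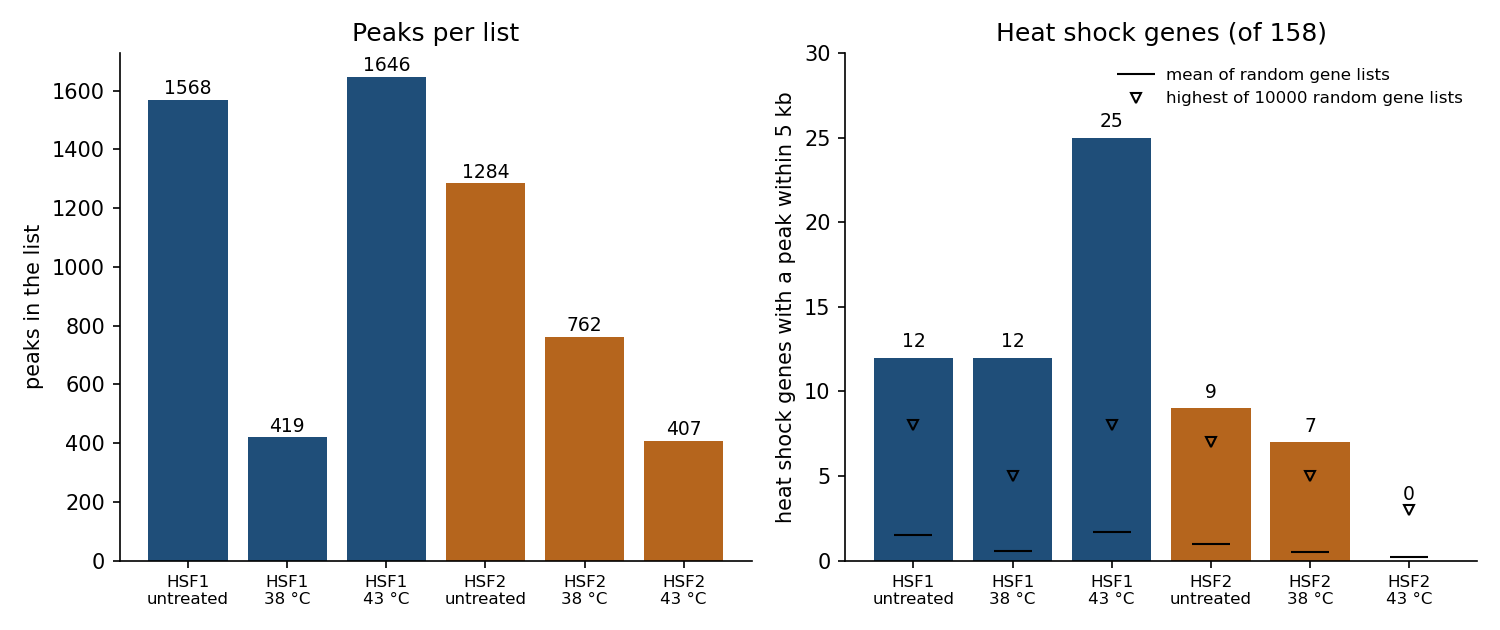
Bars give the number of peaks in each of the 6 lists (left) and the number of 158 heat shock genes with a peak within 5 kb of the TSS (right), with the calculated mean for random gene lists (dash) and the highest value of 10000 such lists (triangle). The heat shock gene count was 25 in the HSF1 list at 43 °C and 0 in the HSF2 list at 43 °C.

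Several of the genes shared by most lists code for cytosolic chaperones and their partners. Hsp90aa1, an inducible form of the HSP90 chaperone, had a peak over its promoter in 5 lists, all but HSF2 at 43 °C. It was the highest scoring peak in untreated cells for HSF1 (chromosome 12, 110696083 to 110696507, mm10, score 402) and for HSF2 (110696293 to 110696492, score 233), and also for HSF1 at 38 °C (score 597). At 43 °C the HSF1 peak there ranked 10 of 1646. St13, a partner of HSP70, and Hspa8, the constitutive HSP70, had promoter peaks in the same 5 lists. At 43 °C the HSF1 peak at St13 reached to 81400233 on chromosome 15 and also covered an end of Xpnpep3, at 81400105. The Hspa8 peak spanned 40800929 to 40801516 on chromosome 9 at 43 °C, where it ranked 4 with a score of 705. Stip1, which links HSP70 to HSP90, was in 4 lists and ranked 6 of 1646 for HSF1 at 43 °C (chromosome 19, 7039719 to 7040074). Hsp90ab1, the constitutive HSP90, had no peak in the untreated HSF1 list. It ranked 3 for HSF1 at 38 °C and 1 at 43 °C, with a score of 1384, at 45573810 to 45574066 on chromosome 17 and at a distance of -677 bp to the TSS. In the HSF2 lists the Hsp90ab1 peak ranked 99 of 1284 in untreated cells and 573 of 762 at 38 °C.

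The mitochondrial chaperonin genes Hspd1 and Hspe1 share a promoter, and peaks lay over it in 5 lists. The authors' annotation gave Hspd1 as the nearest gene of the HSF1 peak at 43 °C (chromosome 1, 55087691 to 55088366, rank 2, score 1176) and Hspe1 for the other 4. The promoter class named the same transcript for all 5, so each gene alone understates the sites. When every gene assigned to a merged region was counted, a choice made after seeing the data, the HSF1 list at 43 °C held 27 heat shock genes, with Hspe1 and Dnaja1 added. Dnaja1, a DNAJ partner of HSP70, had a promoter peak for HSF1 at 38 °C and for HSF2 in untreated cells, while the overlapping HSF1 peak at 43 °C was given to the non-coding gene Gm6297.

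At 43 °C HSF1 also lay at heat shock genes that no other list contained. Dnajb1, the inducible DNAJ partner of HSP70, ranked 11 of 1646 (chromosome 8, 83608025 to 83608324, over the TSS, score 298). Hspa1a and Hspa1b, the strongly inducible HSP70 genes, ranked 13 and 12, and their peaks on chromosome 17 (34972172 to 34972421 and 34959254 to 34959503) had the same score of 292 and the same distance to the TSS. These genes are near-identical copies, so reads can be split between them and either assignment is uncertain. Dnaja4 ranked 15, Cacybp 21 and Zfand2a, a stress-induced partner of the proteasome, 38. P4ha1, Ahsa1, which activates the HSP90 ATPase, Hspa9, the mitochondrial HSP70, Cct8 and Hsp90b1, the HSP90 of the endoplasmic reticulum, followed at ranks 130, 259, 466, 670 and 710. The Cct8 peak was annotated at the promoter of a non-coding transcript, so its gene is uncertain. Cct3 and Cct5, subunits of the cytosolic chaperonin, and Hspd1 complete the 14. The authors' annotation names Hspd1 in this list alone, though its promoter had peaks in 5 lists. Cct3 and Cct5 fall outside the rule for named genes and were added after their values were seen.

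Further heat shock genes had peaks in various lists, and only some of them at both heat shock temperatures. Chordc1, an HSP90 partner, and Hspa4l, an HSP110 relative with a role in spermatids, had HSF1 promoter peaks at 38 °C and 43 °C and in no other list, and Hsph1, which codes for HSP110, had them there and for HSF2 at 38 °C. Ptges3, an HSP90 co-chaperone, had peaks for HSF1 at 43 °C and HSF2 at 38 °C, and Cct6a for HSF1 at 43 °C and HSF2 in untreated cells. Nudc, Dnajc7 and Dnajc3 had peaks only in the untreated HSF1 list among the 6, Jun only for HSF1 at 38 °C, and Hspb3 only for untreated HSF2. Dedd2, Dnajc1 and Tcp1, in the untreated HSF1 list alone, were outside the naming rule and were added after their values were seen. No member of the heat shock factor family had a peak within 5 kb.

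**Figure D2:**
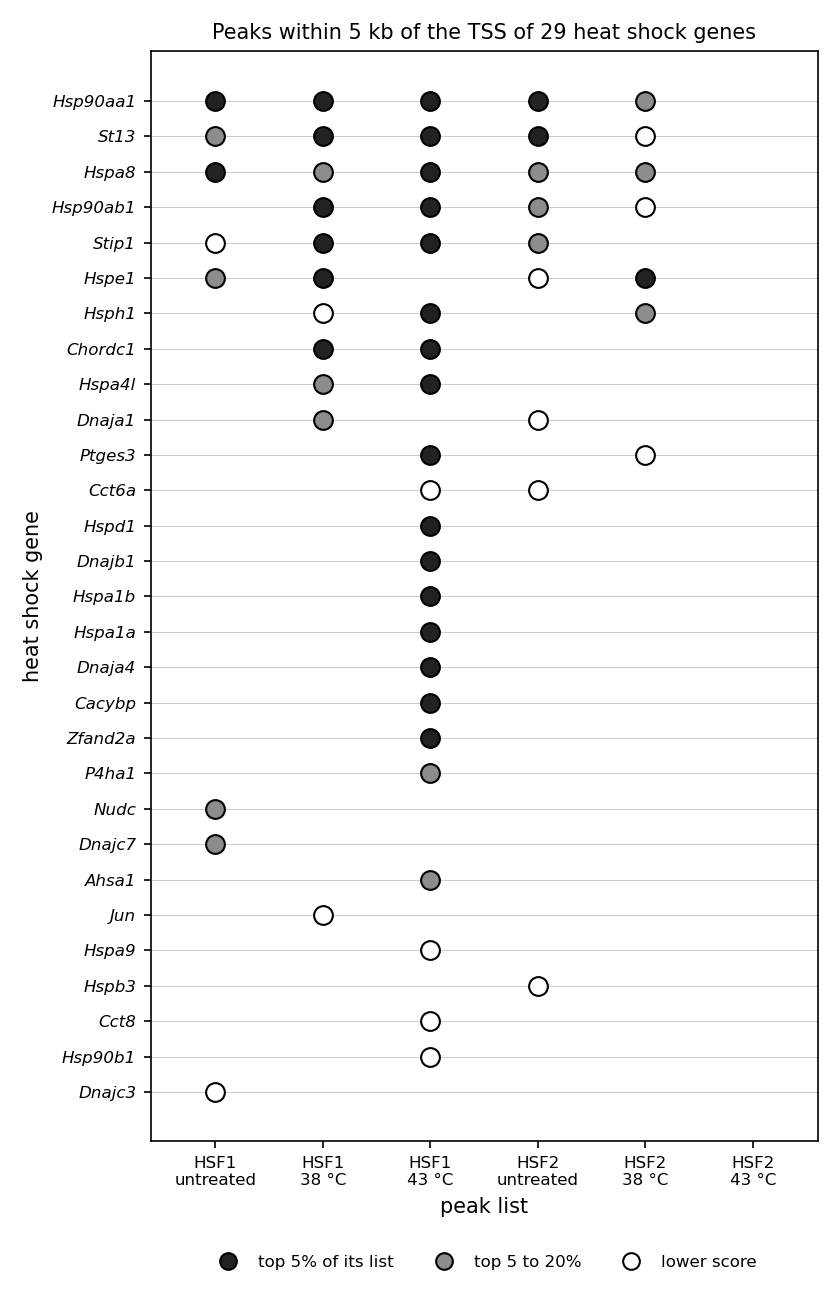
Each row is 1 of 29 heat shock genes and each column a peak list; a circle marks a peak within 5 kb of the TSS in the authors' annotation, black for the top 5% of that list by score, grey for the top 5 to 20% and white for lower scores. In the HSF1 list at 43 °C 16 of its 22 marked genes are black, the HSF2 column at 43 °C is empty, and Hspd1 and Hspe1 share a promoter.

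By family, HSP70 and HSP110 genes with an HSF1 peak numbered 1 of 15 in untreated cells (Hspa8), 3 at 38 °C and 6 at 43 °C, and the random lists would average 0.159 for the 43 °C list. HSP90 and its partners numbered 3, 5 and 8 of 24, and the random lists would average 0.254 at 43 °C. DNAJ genes numbered 3, 1 and 2 of 47, which 0.94%, 16.0% and 8.94% of random lists equalled or passed. Small heat shock proteins and chaperonins numbered 2, 1 and 5 of 28, and the other heat shock targets 3, 2 and 4 of 37. For HSF2 the HSP90 group had 4 of 24 members with a peak in untreated cells and 4 at 38 °C, the HSP70 group 1 and 2 of 15, the small heat shock proteins and chaperonins 3 and 1 of 28, the DNAJ genes 1 and 0 of 47, and the other targets 0 at every temperature.

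The lists for other cell functions had few peaks. Of 69 meiosis genes, 0 had an HSF1 peak in untreated cells, 3 at 38 °C and 5 at 43 °C, and 0.31% and 0.04% of random lists had as many as the heated lists. Spo11, the enzyme that cuts DNA to begin meiotic recombination, had a peak in its first intron for HSF1 at 38 °C (chromosome 2, 172980076 to 172980255, rank 10 of 419) and at 43 °C (172980100 to 172980488, rank 53), and for HSF2 in untreated cells (rank 267 of 1284). The peak of rank 53 is annotated as a simple repeat and the other peaks are not, among them a second HSF1 peak at 43 °C over the promoter (rank 1568). Piwil2, which acts in the silencing of transposons, had peaks in both heated HSF1 lists, but they did not overlap. The peak at 38 °C lay over the promoter (rank 309 of 419) and that at 43 °C in the first intron (rank 859 of 1646). Tdrd9 and Mdc1 had peaks in the HSF1 list at 43 °C. For HSF2, 3 of the 69 had a peak in untreated cells, which 0.97% of random lists reached, and 0 had one after heating.

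Spermatid genes with peaks were Hspa4l and Fabp9 in both heated HSF1 lists, Spata16 for untreated HSF1 and Spag4 for untreated HSF2, 4 of 59, where random lists would average 1.82 over all lists of peaks. Of 58 ubiquitin and proteasome genes 3 had a peak in any list, among them Ubqln1 for HSF1 at 43 °C and untreated HSF2 and Rad23b for untreated HSF1, where random lists would average 1.79. Apoptosis genes were Pmaip1, a BCL2 family killer protein, in both heated HSF1 lists and Endog for HSF2 at 38 °C, 2 of 41 (random lists 1.27). Of 43 multicopy and sex-linked genes only Luzp4 had a peak, for untreated HSF2 (random lists 1.33). Among markers of other testis cells, 0 of 20 Sertoli cell genes, 1 of 19 spermatogonia genes (Kit) and 1 of 18 Leydig, peritubular and macrophage genes (Myh11) had a peak in any list, where random lists would average 0.619, 0.588 and 0.557. Of 29 housekeeping genes 3 had a peak in any list, among them Rpl7 and Eef1a1, where random lists would average 0.897.

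The second question was where peaks lay in relation to genes. The HSF1 list at 38 °C had the largest share of promoter peaks, 12.4% (Wilson 95% interval 9.59% to 15.9%), against 5.29% (4.29% to 6.51%) in untreated cells and 6.62% (5.52% to 7.93%) at 43 °C. For HSF2 the share was 2.80% (2.03% to 3.86%) in untreated cells, 3.67% (2.55% to 5.26%) at 38 °C and 1.47% (0.677% to 3.18%) at 43 °C. When each list was limited to its 407 highest scoring peaks, cut by position where scores tied, the HSF1 share at 43 °C was 12.8%. That was close to the share at 38 °C. Introns held 32.2% to 40.3% of peaks and intergenic sequence 43.7% to 61.0%. Simple repeats held 6.31%, 7.64% and 14.9% of HSF1 peaks in untreated cells, at 38 °C and at 43 °C, and 4.91%, 8.40% and 18.9% of HSF2 peaks. Repeats of CA or TG made up 120 of the 246 simple repeat peaks of HSF1 and 31 of the 77 of HSF2 at 43 °C. Chromosome X held 1.79% to 3.10% of the peaks of a list and chromosome Y 0.246% to 2.15%.

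The third question was which sites an antibody kept across temperatures. HSF1 at 38 °C and 43 °C shared the most: 58 of the 419 peaks at 38 °C, or 13.8% (10.9% to 17.5%), overlapped a peak at 43 °C by at least 1 bp, and 34 of the 58 lay within 5 kb of a TSS. The untreated HSF1 list shared 24 of those 419 peaks, 5.73% (3.88% to 8.38%), with the 38 °C list. It shared 23 of its own 1568 peaks, 1.47% (0.979% to 2.19%), with the 43 °C list. For HSF2 the 38 °C list shared 8 of 762 peaks, 1.05% (0.533% to 2.06%), with untreated cells. The 43 °C list shared 7 of 407, 1.72% (0.836% to 3.51%), with the 38 °C list, of which 3 were in simple repeats, and 0 of 407 with untreated cells, which allows a share of up to 0.737%. In 1000 random placements within the same chromosome the mean number shared was 0.098 for the HSF1 lists at 38 °C and 43 °C and at most 0.439 for any of these pairs, and no placement gave more than 4.

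After overlapping peaks of all lists were merged, 5810 of 5925 regions, 98.1%, were in 1 list, 115 in 2 or more, 29 in 3 or more, 10 in 4 or more, 5 in 5 and 0 in 6. The 5 regions in 5 lists lay at Hsp90aa1, St13, Hspa8, the shared promoter of Hspd1 and Hspe1, and Uspl1, a gene for a SUMO protease on chromosome 5. The Uspl1 peak at 149184181 to 149184705 ranked 3 of 1646 for HSF1 at 43 °C. The 5 regions in exactly 4 lists lay at Hsp90ab1, Stip1, Acot7, Ube2g2 and Slc35e2. Of the 29 regions in 3 or more lists 22 lay within 5 kb of a TSS, 8 were at heat shock genes and 3 overlapped simple repeats. Recurrence was highest among the peaks with the highest scores. In the HSF1 list at 38 °C 36.9% (27.4% to 47.6%) of the 20% of peaks with the highest scores overlapped a peak of another list, against 9.64% (4.96% to 17.9%) of the 20% with the lowest. For HSF1 at 43 °C the shares were 15.5% and 3.65%, but the parts between had 0.304%, 4.86% and 0.608%, so recurrence did not fall steadily with score. Highest and lowest parts had 6.05% and 3.2% for untreated HSF1, and 3.89% and 2.73% for untreated HSF2, a small contrast. For HSF2 they had 12.4% and 3.95% at 38 °C, and 8.54% and 2.47% at 43 °C. Tied scores, common at 43 °C, were ordered by position.

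**Figure D3:**
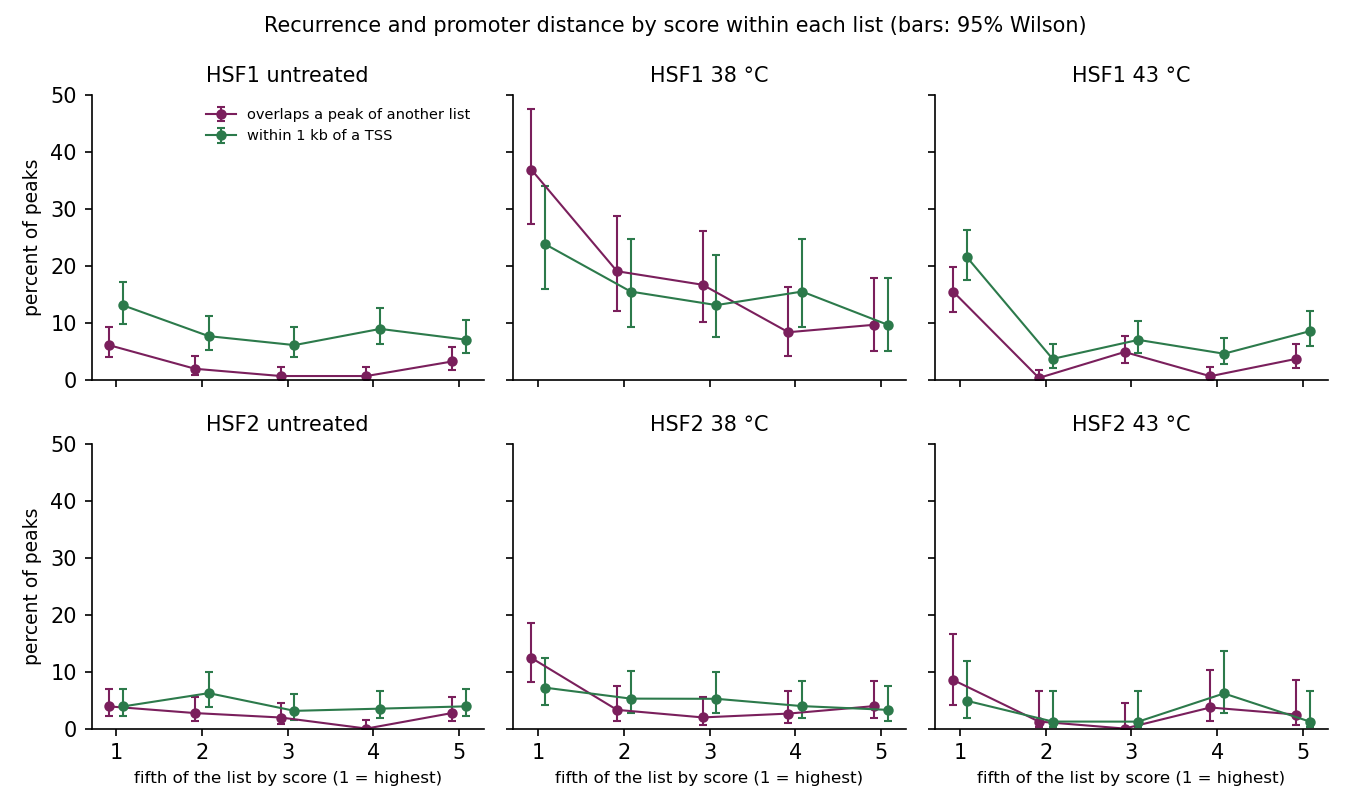
Percent of peaks that overlap a peak of another list (purple) and that lie within 1 kb of a TSS (green) in 5 parts of each list, from the highest scores (1) to the lowest (5), with 95% Wilson intervals. Recurrence was 36.9% in the first and 9.64% in the last part of the HSF1 list at 38 °C.

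The fourth question was how far HSF1 and HSF2 lay at the same sites at one temperature. In untreated cells 11 of the 1284 HSF2 peaks, 0.857% (0.479% to 1.53%), overlapped an HSF1 peak, at 38 °C 16 of the 419 HSF1 peaks, 3.82% (2.36% to 6.11%), overlapped an HSF2 peak, and at 43 °C 4 of the 407 HSF2 peaks, 0.983% (0.383% to 2.50%), overlapped an HSF1 peak. Random placements gave means of 0.345, 0.06 and 0.093. The untreated pair had 9 genes in common, where independent lists would share 1.53, and at 38 °C the pair had 11, where 0.314 would be shared. At 43 °C the pair had 2 genes in common, Slc25a38, which carries glycine into mitochondria, and Cartpt, which was named after its values were seen. The other 2 shared peaks lay in simple repeats. HSF1 and HSF2 lists of the same temperature share a mock library, and part of these overlaps may come from it. HSF1 and HSF2 lists with different mock libraries also overlapped: 18 of the 419 HSF1 peaks at 38 °C overlapped an untreated HSF2 peak, and 21 of the 1284 untreated HSF2 peaks an HSF1 peak at 43 °C. Of the 762 HSF2 peaks at 38 °C, 17 overlapped an HSF1 peak at 43 °C and 13 an untreated HSF1 peak. Of the 407 HSF2 peaks at 43 °C, 2 overlapped an HSF1 peak at 38 °C, where placements averaged 0.022 and 0 of 1000 gave as many, and 1 an untreated HSF1 peak, where they averaged 0.13 and 124 of 1000 gave as many. Hsp90aa1, Hspa8, St13, Hspe1 and Uspl1 had both factors in untreated cells and at 38 °C.

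The last question was which genes had a nearby peak only with or only without heat. Genes with a peak within 5 kb of the TSS numbered 252, 98 and 279 for HSF1 in untreated cells, at 38 °C and at 43 °C, and 160, 85 and 39 for HSF2. Of 814 such genes in all, 62 were in 2 or more lists and 30 had both factors. For HSF1, 20 genes had a peak in both heated lists and not in untreated cells, 13 in all 3 lists and 229 in untreated cells alone. The first set, by rank, was led by Hsp90ab1, Pknox1, Spo11, Hsph1, Chordc1, Hspa4l, Slc25a38, Gm10069, Fxr1 and Art3. An overlapping HSF2 peak at 38 °C, also given to Gm10069, was annotated at the promoter of another, protein-coding transcript. The Gm10069 site may therefore belong to a neighbouring gene that the counts by gene miss. Pknox1, a homeobox gene, had peaks in its first intron on chromosome 17 at 31565080 to 31565459 (rank 7 of 419) and at 31564964 to 31565367 (rank 17 of 1646), and Fxr1, an RNA-binding protein gene of the germ line and muscle, had promoter peaks at rank 105 of 419 and 39 of 1646. The HSF1 lists at 38 °C and 43 °C had 33 genes in common, where independent lists would share 1.04. The untreated list shared 18 with each, where 0.934 and 2.65 would be shared.

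The 229 genes of the untreated HSF1 list alone were led by Rn45s, Ipo13, Mir1960, Cbx5, Rbm25, Fer1l5, Col2a1, Matn1, Actr3 and Zfp661. Rn45s, the ribosomal RNA precursor, had a peak of 5908 bp on chromosome 17 (39842968 to 39848875) that overlapped the peak of rank 2 in the HSF2 list at 38 °C. Cbx5 also had a peak in that HSF2 list (rank 352 of 762). For HSF2, 1 gene, Mir466d, was in both heated lists and not in untreated cells, 148 were in untreated cells alone and 0 were in all 3 lists. Those of high rank among the 148 were D4Wsu53e, Epc1, St18, Nek10, Mfsd7b, Slc5a10, Cd7, Slc45a4 and Stip1. Of these, D4Wsu53e (chromosome 4, 134923533 to 134923666, rank 3) also had an HSF1 peak at 43 °C, and Stip1 had HSF1 peaks in all 3 HSF1 lists. Epc1 and St18 had theirs 4969 and 4758 bp downstream of the TSS.

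The highest scoring peaks differed in kind between lists. Of the top 20 peaks, those at heat shock genes numbered 1, 7 and 13 for HSF1 in untreated cells, at 38 °C and at 43 °C, and 2, 1 and 0 for HSF2. Those in simple, satellite, low complexity, ribosomal RNA or 7SL RNA repeats numbered 6, 1 and 1 for HSF1, and 5, 15 and 5 for HSF2. After Hsp90aa1 and Rn45s, the untreated HSF1 list had an intronic repeat on chromosome 5 (22786074 to 22786590, nearest gene A930003O13Rik), then the promoters of Acot7, Pradc1 and Arhgef1. At 38 °C HSF1 ranked Hsp90aa1, Uspl1, Hsp90ab1, St13 and, at rank 6, Hspe1 first near a TSS. At 43 °C it ranked Hsp90ab1, Hspd1, Uspl1, Hspa8 and Azi2. The untreated HSF2 list began with Hsp90aa1, St13 and D4Wsu53e, followed near a TSS by Epc1 and Uspl1.

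In the HSF2 list at 38 °C the highest score, 1153, belonged to an intergenic simple repeat on chromosome 17 (4626123 to 4626638, nearest gene Arid1b), followed by Rn45s and a repeat on chromosome 14 (104336888 to 104337090, nearest gene Pou4f1). Near a TSS the leaders were Rn45s, Hspe1 (rank 10), Birc6 (28), Uspl1 (37) and Cdc27 (43). In the HSF2 list at 43 °C the highest score, 210, belonged to an intergenic peak of 4644 bp on chromosome 1 (24611551 to 24616194, nearest gene Col19a1) that overlies the pseudogenes Gm10222 and Gm10925, followed by the promoter of Mir466d and an intron of Hgsnat. The next peaks near a TSS, at Il17f, Popdc3, Rhob and Serpina5, all had the same score of 79.7.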

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

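The test of how often the lower-scoring peaks recur was set before its result was seen, and the other tests in this part were chosen after.

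HSF1 and HSF2 lists differed from untreated cells in opposite directions for some measures and in the same direction for others, and with 1 list per group none of these differences was tested. From untreated cells to 43 °C the number of peaks differed by 78 for HSF1 and by -877 for HSF2. Genes with a peak within 5 kb differed by 27 and -121, and heat shock genes with a peak by 13 and -9. The promoter share differed by 1.33 percentage points for HSF1 and by -1.33 for HSF2, and the share of peaks within 5 kb of a TSS by 0.988 and -2.71 points. From untreated cells to 38 °C the share within 5 kb of a TSS differed by 7.06 points for HSF1 and by -1.38 for HSF2, while the number of peaks differed by -1149 and -522 and the promoter share by 7.12 and 0.871 points. The share of simple repeats was above that of untreated cells for both factors at both temperatures.

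Most peaks occurred in a single list. Too few calls in the shorter lists are not the whole cause, since the untreated and 43 °C HSF1 lists, of about the same length, shared 1.47% of peaks. Background calls that differ from library to library may account for part of it: 2.69% (2.18% to 3.33%) of the lower-scoring peaks of the 6 lists overlapped another list, against 6.38% (5.56% to 7.30%) of the higher-scoring ones. The long lists weigh most in these pooled shares: in the HSF1 list at 38 °C 9.05% of the lower-scoring peaks recurred, against 27.3% of the higher-scoring ones. The contrast was small in the untreated HSF2 list (1.56% against 2.96%) and the HSF2 list at 43 °C (2.45% against 3.94%). In the latter the median score was shared by 163 of 407 peaks, ordered by position, so its split need not follow score. Sites truly used at a single temperature stay open, since no list has a replicate.

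The HSF2 list at 43 °C had no heat shock gene. The same number of top peaks of the untreated HSF2 list held 8 heat shock genes, so a list of this length can hold such genes. A list kept short by low read depth or weak signal stays open. The lowest scores of both lists were alike, 50.07 untreated and 50.15 at 43 °C, and depth is unknown, so weaker peaks could have dropped out. A poor precipitation or library cannot be told apart from loss of HSF2 from these promoters, with 1 list in the group: 3.19% (1.88% to 5.39%) of its peaks overlapped another list, above the highest of the random placements, 0.983%. Of those 13 recurrent peaks 8 lay in simple, ribosomal RNA or 7SL RNA repeats.

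The highest scoring HSF2 peaks at 38 °C lay in repeats, 15 of the top 20. HSF2 bound to repeat units that hold GAA or TTC, the core of a heat shock element, stays open as part of the cause. Of the 15, 8 lay in such units and 6 in ribosomal RNA or 7SL RNA repeats, whose sequence was not searched. The other 1, the highest scoring peak of the list, lay in a unit that lacks GAA and TTC. Such units therefore do not cover every peak. Simple repeats of GAATG or CATTC held 13 peaks of this list, 1 at 43 °C for HSF2 and 0 in each other list. Such units hold GAA or TTC, so their number does not tell HSF2 binding from DNA of another organism. DNA of another organism in the library also stays open. Ribosomal RNA and 7SL RNA repeats held 3.02% of the peaks, against 0.061% to 0.983% in the other 5 lists, but these repeats are part of the pattern itself, so the share gives that explanation no support of its own. Reads of repeats placed at too few sites in the reference stay open as well, and were not tested.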

How the results depend on the processing

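Counting every gene of a merged region, and leaving out the HSF2 list at 38 °C or at 43 °C, were alternatives chosen after the data were seen, and the others were chosen before. Each choice was changed on its own. Of 246 alternative values for the results that answer a comparison, 173 stayed within the counting error or within 1.5 times the reported count, 30 were higher and 43 lower. Of 576 values for named genes 518 stayed, 10 were higher and 48 lower, and of 720 for single gene lists 637 stayed, 47 were higher and 36 lower. Some alternatives applied to few of the results that answer a comparison and moved none of those: peaks within 500 bp merged (6 values), overlap of 50% of both peaks (9), centres within 1 kb (9), every gene of a merged region (6), and no HSF2 list at 38 °C or at 43 °C (3 each). Leaving out peaks of all 6 lists removed nothing, so its 39 values, with 72 for named genes and 90 for single gene lists, had to stay. The 6 numbers of peaks in the higher-scoring 50% of each list had to be lower. The totals above include these values. Heat shock elements gave no values, since no genome sequence was used. Placements that kept the share near a TSS gave 0.062 to 0.625 shared peaks on average and moved 2 of 9 means, to 0.18 (HSF1 untreated and 38 °C) and 0.199 (HSF1 38 °C and 43 °C). Values below follow the order HSF1 untreated, 38 °C and 43 °C, then HSF2, and causes were not tested unless fewer peaks or a wider or narrower distance make them so by construction.

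With the higher-scoring 50% of each list, peaks numbered 784, 209, 823, 642, 381 and 203 and genes near a TSS 139, 55, 160, 88, 46 and 16. The HSF1 promoter share at 43 °C was 8.38%. Shared peaks numbered 15 for HSF1 untreated and 43 °C, 34 for HSF1 38 °C and 43 °C, 8 for HSF1 and HSF2 at 38 °C and 1 at 43 °C. Genes in 2 or more lists numbered 37, HSF1 genes in both heated lists alone 11, and genes of untreated cells alone 124 for HSF1 and 83 for HSF2. With 407 top peaks per list, the HSF1 promoter share was 8.11% untreated and 12.8% at 43 °C. Shared peaks numbered 12 for HSF1 untreated and 43 °C, and 7, 10 and 2 for HSF1 and HSF2 untreated, at 38 °C and at 43 °C. Genes near a TSS numbered 79 (HSF1 untreated), 108 (HSF1 43 °C), 55 (HSF2 untreated) and 49 (HSF2 38 °C), with 36 in 2 or more lists, 19 for both antibodies, and 66 (HSF1) and 50 (HSF2) in untreated cells alone. Heat shock genes of untreated HSF1 numbered 7. Without peaks on chromosome Y, on unplaced sequence or in simple, low complexity, satellite or ribosomal RNA repeats the HSF1 promoter share at 43 °C was 8.04%, and shared peaks numbered 2 for HSF1 and HSF2 at 43 °C and 4 for HSF2 38 °C and 43 °C. The share within 1 kb of a TSS, in place of the promoter class, was 8.55% (HSF1 untreated), 9.05% (HSF1 43 °C) and 4.13% (HSF2 untreated).

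Within 1 kb of the TSS genes numbered 131, 65, 143, 53, 38 and 12, with 112 (HSF1) and 47 (HSF2) in untreated cells alone. Within 10 kb they numbered 427 for HSF1 at 43 °C and 247, 149 and 74 for HSF2, with 348 (HSF1) and 234 (HSF2) in untreated cells alone and 3 in both heated HSF2 lists alone. At any distance they numbered 1421, 410, 1498, 1169, 705 and 397, with 935 in 2 or more lists, 620 for both antibodies, 61 (HSF1) and 27 (HSF2) in both heated lists alone, and 1130 (HSF1) and 1000 (HSF2) in untreated cells alone. Heat shock genes then numbered 19 for HSF1 untreated and 15, 11 and 1 for HSF2, the last being Dnajc1, named after its value was seen. Read depth, which limits the length of every list, was not analysed here.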

Other observations

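The observations in this part were chosen after the data were seen, and no test was run on them.

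Several genes outside the heat shock lists had recurrent peaks at their promoters. Azi2, a gene of innate immune signalling, and Pradc1 had HSF1 peaks in all 3 HSF1 lists, on chromosome 9 at 118040406 to 118040739 and chromosome 6 at 85451841 to 85452241. Acot7, an acyl-CoA thioesterase, and Ube2g2, a ubiquitin-conjugating enzyme of protein degradation at the endoplasmic reticulum, had peaks in all 3 HSF1 lists and in the untreated HSF2 list. Aldh1a2, which makes retinoic acid, had promoter peaks for HSF1 in untreated cells and at 43 °C and for HSF2 at 38 °C (chromosome 9, 71215253 to 71215622). Hnrnpa2b1 had promoter peaks for HSF1 at 43 °C and HSF2 at 38 °C (chromosome 6, 51469618 to 51470114). Zcwpw2 ends at 118040859, beside the Azi2 region, and Cbx3 begins at 51470154, beside the Hnrnpa2b1 region. These sites may therefore belong to either gene.

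Regions far from any TSS also recurred. Merged regions in all 3 HSF1 lists and in no HSF2 list, with no TSS within 5 kb, lay, apart from the repeat near A930003O13Rik, in introns, nearest to Trhr2 (chromosome 8, 122332428 to 122332843) and Grin2b (chromosome 6, 136057453 to 136057716), and in intergenic sequence nearest to Dnmt3b (chromosome 2, 153694596 to 153694950) and to G530011O06Rik (chromosome X, 169997784 to 169998412).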
